A study of Homo sapiens with 18 samples.

How the data were processed

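RNA was sequenced from PA1 cells, a human embryonal carcinoma line. Per the labels' protocols, lysates of cells with FLAG-tagged LIN28A, wild-type or S200D, and of parental cells without FLAG were passed over anti-FLAG beads, RNA was isolated from the beads, polyA-selected and made into libraries. Input libraries of the same lines were made from RNA before the IP. The labels give 6 groups of 3 libraries, and group and replicate number were taken from the sample titles. Nothing in the sources states that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

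The deposited values are RPKM, reads scaled to gene length and library size, made by the authors with 1 column per library. Per the submitters' processing notes, cutadapt, TopHat2, HTSeq and the genome build hg19 were used, while versions, gene annotation and strand setting are not given in the sources used here. The table holds 25855 genes, 21363 of them above 0 in at least 1 library, and no column was left out. Low values are whole multiples of a step set by the gene and the library, so whole reads were recovered: 100% of values above 0 were whole within a tolerance of 0.02 reads. The recovered reads in genes ran from 21311007 to 44195194 per library. The denominators of the deposited RPKM differ from these totals by factors between 0.812 and 1.129, which match trimmed-mean scaling factors computed here within 8e-05. Against total reads, this scaling raises WT_IP over Ctrl_IP, so that the step to total reads is a shift of -0.42, and -0.40 for S200D_IP. Replicates of 1 group differed by more than sampling noise, with chi-square per degree of freedom from 8.57 to 55.0, so none was counted as a repeat of another. Gene classes, transcripts and coding sequences came from a RefSeq table of the assembly GRCh38.p14 and from GENCODE v29, which are of another build and were used through gene symbols, without coordinates: 11545 of the 11679 tested genes had a class, 10905 of them protein coding and 226 small non-coding RNA genes. Gene lengths are those implied by the RPKM steps.

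Tests were made on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, using group means, contrasts and moderated variances with a mean-variance trend, over 11679 genes with a mean RPKM of at least 1. Adjusted p values are Benjamini-Hochberg values within a comparison, and a gene was called at an adjusted p under 0.05. Comparisons among IPs used the 9 IP libraries, those among inputs the 9 input libraries, and those of IP with input, with their differences between lines, all 18. There were 12 comparisons of genes and 7 of gene lists. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. That estimate came from a fit without replicate numbers, so deviations shared by libraries of the same number enter it. Of 22 lists, 19 had at least 5 tested genes. Endoderm markers and trophoblast and keratin markers had 4 each, and the list of transcripts of the mitochondrial genome had 0. LIN28A was kept out of every list. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served the other steps.

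Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took LIN28A first, then the 10 largest and 10 smallest log2 differences in main comparisons and 5 of each elsewhere, among called genes whose 3 libraries of 1 group all lay on the same side of the 3 of the other and whose higher group had a mean of at least 5 RPKM. It added up to 4 members with the smallest adjusted p of each list described and a fixed panel of genes in every IP comparison, and fewer were named where space was short. A gene of the panel is not reported here. Equivalence was tested after the main counts were seen, with 2 one-sided tests per gene and Benjamini-Hochberg adjustment. Its margins were 2-fold and 1.5-fold in RPKM + 1.

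Replicate numbers appear in the titles of every group. Deviations from group means of libraries with the same number in other groups correlated at 0.22 to 0.62 (median 0.38, 45 pairs), and those with other numbers at 0.04 at most, so the numbers pair the samples. The test was fixed without the replicate number, and a fit with it as a block was an alternative. The other alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, a mean of at least 5 RPKM, median scaling, quantile normalization, robust variance moderation, another set of libraries in the fit, an estimated correlation for lists, and leaving out each library. Total reads as the scale, voom weights on recovered reads, the table without small non-coding RNA genes, lower genes shared by both FLAG IPs on other scales, overlaps of the top genes of simulated groups, list tests outside the 7 comparisons, and leaving out a replicate number in every group were chosen after seeing the data.

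The steps were tested on simulated data with 200 genes changed by known folds, drawn from the means, spreads and depths of the real libraries. Libraries were drawn independently, without the pairing of replicate numbers. For WT_IP against Ctrl_IP, 28.4% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 92.4% of those changed 4-fold were found among 11679 genes. The list test was run with a list raised by 0.5 on the log2 scale. With cell cycle genes raised, 3 of 19 lists passed, the raised list and 2 others that share genes with it. The mitochondrial ribosome was raised as well, after that result was seen, and 1 of 19 lists passed, the raised list.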

Results

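RNA that co-purified with the RNA-binding protein LIN28A was measured in PA1, a human embryonal carcinoma cell line, by sequencing polyA-selected RNA after immunoprecipitation (IP) with an anti-FLAG antibody. LIN28A is known to bind mRNAs and the precursors of let-7 microRNAs and to be high in pluripotent cells. The 18 libraries fall into 6 groups of 3. Cells carried FLAG-tagged wild-type LIN28A (WT), FLAG-tagged LIN28A with the phospho-mimetic change S200D, or no FLAG transgene (Ctrl). Each line was sequenced after the IP and as input RNA. The libraries held between 21311007 and 44195194 reads in genes, and 11679 genes with a mean of at least 1 RPKM were tested. Differences are on the scale of log2(RPKM + 1), which understates changes of low genes. Errors of log2 differences are standard errors from limma, and group levels are means ± SD with n = 3.

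LIN28A itself had similar levels in the 3 inputs, at 479.5 ± 20.2 RPKM in Ctrl_Input, 470.9 ± 28.3 in WT_Input and 470.9 ± 28.7 in S200D_Input. After the IP it stood at 429.6 ± 20.1 RPKM in Ctrl_IP, 338.7 ± 29.6 in WT_IP and 341.9 ± 31.9 in S200D_IP. LIN28A was lower in WT_IP than in Ctrl_IP by limma (log2 difference -0.34 ± 0.10, adjusted p = 0.0116). Reads of the transgene and of the endogenous gene share this value, so it checks no label.

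The first comparison set each FLAG IP against the no-FLAG IP, which asks which RNAs make up more or less of the FLAG IPs than of the background of the beads. The amount of RNA recovered by each IP is not part of these values. A gene lower in a FLAG IP thus has a smaller share of its library, scaled as deposited, and need not have been recovered less. Short mRNAs of the ribosome and of the mitochondrial respiratory chain stood out. NDUFB3, a subunit of respiratory complex I, rose from 54.2 ± 1.40 RPKM in Ctrl_IP to 385.3 ± 33.9 in WT_IP (log2 difference 2.8 ± 0.095, adjusted p = 3.68e-08) and to 371.3 ± 30.8 in S200D_IP (2.75). RPL9, a protein of the large ribosomal subunit, rose from 439.5 ± 3.25 to 2747 ± 243.8 RPKM in WT_IP (2.64 ± 0.11), which ranked behind S100A2, RNF7, GGH and PET100, and to 2717 ± 396.4 in S200D_IP (2.61). The others of the 10 largest increases in WT_IP were S100A2 (2.67 ± 0.21), RNF7, a ubiquitin ligase subunit (2.66 ± 0.095), GGH, a folate hydrolase (2.65 ± 0.11), PET100 (2.64 ± 0.15), AES (2.64 ± 0.14), SEC11C, a signal peptidase subunit (2.63 ± 0.095), CHCHD1 (2.54 ± 0.10) and UQCRH, a subunit of respiratory complex III (2.53 ± 0.092).

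Small non-coding RNA genes lay at the other end. MIR3064 (-4.11 ± 0.37), MIR367 (-3.97 ± 0.38), SNORD54 (-3.95 ± 0.50), SNORD49B (-3.87 ± 0.36), MIR5047 (-3.87 ± 0.38), SNORD50B (-3.65 ± 0.38), SNORD49A (-3.62 ± 0.38), MIR302B (-3.60 ± 0.33), MIR302D (-3.56 ± 0.37) and SNORD35B (-3.52 ± 0.15) had the largest decreases in WT_IP. MIR302B fell from 15.4 ± 4.77 RPKM in Ctrl_IP to 0.432 ± 0.748 in WT_IP. Of 226 such genes tested, 116 were lower and 14 higher in WT_IP than in Ctrl_IP, and 121 were lower and 11 higher in S200D_IP. Genes of this kind often lie inside introns of other genes, strand is not stated, and their median of 9.3 reads per Ctrl_IP library is low, so their values are uncertain. The libraries were polyA-selected and these genes have a median length of 83 bases, so the reads may come from longer transcripts that hold them. A lower value thus cannot be read as a decrease of the small RNA itself.

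Over all genes, 6833 of 11679 differed between WT_IP and Ctrl_IP by limma at a Benjamini-Hochberg adjusted p under 0.05, 3554 higher and 3279 lower. At least 2-fold differences were found for 1030 higher and 481 lower genes, a balance that moves with the scale: 452 higher and 1396 lower with total reads as the scale, 685 and 592 with quantile normalization, 1230 and 385 with median scaling, and 1213 and 840 with a pseudocount of 0.1. For S200D_IP against Ctrl_IP the counts were 6822, with 3544 higher, 3278 lower, and 1012 and 464 at 2-fold, or 446 and 1333 with total reads, 684 and 608 with quantile normalization, 1210 and 377 with median scaling, and 1194 and 842 with a pseudocount of 0.1. The deposited values hold a factor per library that sets the balance of directions. Scaled to total reads, the median gene moved by -0.34 in WT_IP and the share of higher genes among the changed ones went from 52.0% to 23.6%. In S200D_IP that share went from 51.9% to 24.3%. Median scaling moved it the other way, to 59.9% and 59.7%, and without a filter it was 49.2% and 49.4%.

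Gene lists fixed before the data were examined were tested with camera in limma at a preset correlation between genes of 0.01. The estimated correlation, whose p-values are given beside it, came from a fit without replicate numbers and may be too high for that reason. Among 77 cytosolic ribosomal protein genes, 73 were higher and 2 lower in WT_IP, with the same counts adjusted over the list alone and a median log2 difference of 1.47 (camera adjusted p = 1.33e-22; adjusted p = 0.463 with an estimated correlation). RPL7 (2.10 ± 0.082), RPS13 (2.5 ± 0.10) and RPL23 (2.27 ± 0.097) were examples. Their share of all reads in genes was 6.60% ± 0.202 in Ctrl_IP, 14.6% ± 0.709 in WT_IP and 14.7% ± 1.68 in S200D_IP. Ribosomal protein genes have many pseudogenes, so reads may have been assigned unevenly among copies.

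Of 74 mitochondrial ribosome genes, 65 were higher and 2 lower, also when adjusted over the list alone, with a median of 0.82 (camera adjusted p = 1.66e-14; adjusted p = 0.463 with an estimated correlation). MRPL11 (2.01 ± 0.093), MRPL41 (2.18 ± 0.11) and MRPS15 (1.61 ± 0.087) were among them. Nuclear genes of oxidative phosphorylation had 60 higher and 5 lower of 76, or 61 and 5 adjusted over the list alone, with a median of 0.80 (camera adjusted p = 1.2e-12; adjusted p = 0.463 with an estimated correlation). NDUFS6 and UQCRB each rose by 2.02 ± 0.090. These 3 lists hold short genes, with median lengths of 837, 1245 and 930 bases against 3289 over coding genes. Across coding genes, length and the WT_IP difference had a rank correlation of -0.37. With the length trend removed, the list medians were 0.66, 0.20 and 0.26. Here and for the lists below, that trend was fitted over all coding genes with the list genes in it, so they help to set it. The medians stayed above 0 with total reads as the scale (1.05, 0.41 and 0.39) and with quantile normalization (0.32, 0.48 and 0.35).

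Translation initiation and elongation factors had 26 higher and 9 lower of 49, also adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.0138; adjusted p = 0.463 with an estimated correlation). EEF1G (2.24 ± 0.096), EEF1B2 (1.8 ± 0.096), EIF3H (1.34 ± 0.086) and EIF3E (1.05 ± 0.083) rose. With quantile normalization the list turned to a median of -0.20 and was lower (camera adjusted p = 0.0416). With total reads as the scale its call ended (adjusted p = 0.1), and its median of -0.10 lay 0.24 above that of all genes. The call also ended at a mean of at least 5 RPKM (adjusted p = 0.072), and the median was 0.18 with the length trend removed. A list of mRNAs named as LIN28 targets in the literature had 21 higher and 5 lower of 36, also adjusted over the list alone, with a median of 0.43 (camera adjusted p = 0.00135; adjusted p = 0.106 with an estimated correlation). NDUFB3, RPS13, EEF1G and NDUFB8 (1.44 ± 0.11) led it, and each of these stands in another list named here as well. Its call ended with quantile normalization (adjusted p = 0.34), and its median was 0.43 with the length trend removed as well. Replication-dependent histone genes had 10 higher and 1 lower of 16, also adjusted over the list alone, with a median of 0.61 (camera adjusted p = 0.0277; adjusted p = 0.781 with an estimated correlation). HIST1H2BK (1.52 ± 0.18) and HIST1H2BD (1.63 ± 0.20) rose, and the median was -0.14 once the length trend was removed. The libraries were polyA-selected, so histone RNA without a polyA tail is not covered by these values. The list also had higher values in the inputs of the FLAG lines, by a median of 0.41 in WT_Input and 0.44 in S200D_Input, and the difference ended once the inputs were taken into account, as given below. Its call ended too at a mean of at least 5 RPKM, with 6 genes tested (adjusted p = 0.103), without Ctrl_IP replicate 1 (0.0544), without WT_IP replicate 3 (0.0523) and without replicate 1 of every group (0.0661).

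Among the lists with lower values in WT_IP, cell-surface, lysosomal and secreted proteins had the smallest p but not the lowest median, with 14 higher and 41 lower of 82, or 16 and 42 adjusted over the list alone (median -0.33, camera adjusted p = 0.0101; adjusted p = 0.463 with an estimated correlation). CD9, a tetraspanin (-2.20 ± 0.21), DSG2, a desmosomal cadherin (-1.24 ± 0.12), and FZD2, a Wnt receptor (-1.22 ± 0.11), were lower, while the lysosomal tetraspanin CD63 was higher (1.98 ± 0.099). CD9 was also lower in WT_Input than in Ctrl_Input (-1.69 ± 0.19). The list has a median length of 4857 bases, and its median was -0.24 with the length trend removed.

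Pluripotency factors had 3 higher and 12 lower of 20, also adjusted over the list alone (median -0.69, camera adjusted p = 0.0161; adjusted p = 0.463 with an estimated correlation). MYCN (-1.59 ± 0.12), SALL1 (-1.12 ± 0.15) and SOX2 (-0.93 ± 0.13) were lower, while POU5F1, which encodes OCT4, was higher (1.10 ± 0.11), with a reservation on its gene model given below. The call of this list ended with total reads as the scale (adjusted p = 0.1). Genes of ERK feedback and the immediate early response had 1 higher and 10 lower of 23, also adjusted over the list alone (median -0.33, camera adjusted p = 0.0138; adjusted p = 0.463 with an estimated correlation), with MYC (-1.37 ± 0.20), SPRY4 (-1.0 ± 0.15) and SPRED2 (-0.62 ± 0.11) lower. Genes of the stress and unfolded protein response had 3 higher and 13 lower of 26, also adjusted over the list alone (median -0.43, camera adjusted p = 0.0268; adjusted p = 0.485 with an estimated correlation). HSPB1 (-1.03 ± 0.11) and HSPH1 (-0.79 ± 0.12), which encode heat shock proteins, were lower, and PPP1R15A (0.81 ± 0.11) and ATF4 (0.55 ± 0.085) higher. With quantile normalization ATF4 turned to -0.23 (adjusted p = 0.0393). The list call ended with total reads as the scale (adjusted p = 0.0543), at a mean of at least 5 RPKM (0.0515), without Ctrl_IP replicate 1 (0.0666) and without WT_IP replicate 3 (0.0505). With the length trend removed the medians of the pluripotency, ERK and stress lists were -0.55, -0.41 and -0.55.

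In a panel of genes named in advance, TARDBP (0.79 ± 0.16), HNRNPA1 (0.74 ± 0.13), HMGA1 (0.86 ± 0.13) and CDK4 (0.45 ± 0.088) were higher in WT_IP. HMGA1 and CDK4 turned to -0.10 and -0.20 with quantile normalization. HSPA5, an endoplasmic reticulum chaperone, fell from 247.6 ± 15.0 RPKM in Ctrl_IP to 110.8 ± 13.9 in WT_IP (-1.16 ± 0.12, adjusted p = 1.23e-05). CCND1 (-0.90 ± 0.20), L1TD1 (-0.74 ± 0.16), IGF2BP3 (-0.72 ± 0.11), SALL4 (-0.66 ± 0.13) and ITGB1 (-0.43 ± 0.13) were lower. LIN28B (-0.08 ± 0.15), IGF2BP1 (0.13 ± 0.12), DICER1 (-0.24 ± 0.13), TIA1 (0.21 ± 0.11), GAPDH (0.33 ± 0.16) and ACTB (0.03 ± 0.13) did not pass the test, and GAPDH and ACTB turned to -1.12 and -1.20 with quantile normalization. NANOG (-0.72 ± 0.26, adjusted p = 0.0355), HMGA2 (-0.37 ± 0.14, adjusted p = 0.0436) and CCNB1 (-0.37 ± 0.15, adjusted p = 0.048) lay close to the threshold. POU5F1 levels cannot be set beside those of other genes, since the length implied by its values was 19454 bases against 1420 for its reference transcript. A gene model of that length may also count reads from outside the POU5F1 mRNA, which was not tested, so its differences between groups are uncertain as well.

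**Figure D1:**
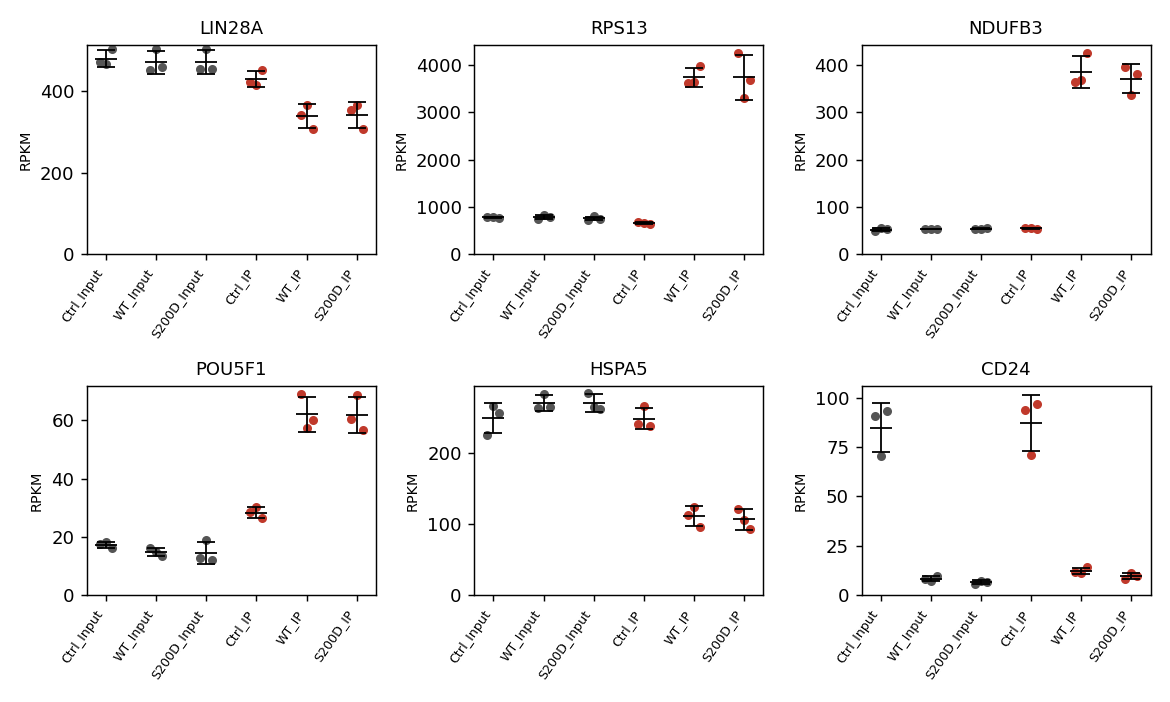
RPKM of 6 genes in each library, by group. Points are libraries, horizontal lines are group means, bars are SD with n = 3, and the y axis starts at 0. NDUFB3 and RPS13 are higher in the WT and S200D IPs than in the other groups, HSPA5 is lower there, and CD24 differs between the parental line and the lines with a transgene in inputs and IPs alike.

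In the S200D IP, set against the same Ctrl_IP libraries, genes of the ribosome and the respiratory chain again had high values and small non-coding RNA genes low values. NDUFB3 (2.75 ± 0.095), GGH (2.69 ± 0.11), AES (2.69 ± 0.14), SEC11C (2.64 ± 0.095), RPL9 (2.61 ± 0.11), RNF7 (2.61 ± 0.095), PET100 (2.58 ± 0.15), S100A2 (2.5 ± 0.21), RPS13 (2.5 ± 0.10) and CHCHD1 (2.48 ± 0.10) led the increases. MIR5047 (-4.27 ± 0.38), SNORD49A (-4.09 ± 0.38), SNORD50B (-3.98 ± 0.38), MIR3064 (-3.78 ± 0.37) and SNORD87 (-3.73 ± 0.29) led the decreases. Of the cytosolic ribosomal protein genes 72 were higher and 2 lower, or 73 and 2 adjusted over the list alone (median 1.44). Of the mitochondrial ribosome genes 62 were higher and 2 lower, or 64 and 3 adjusted over the list alone (median 0.75), and of the oxidative phosphorylation genes 61 and 5, or 62 and 5 adjusted over the list alone (median 0.78). All 10 lists called in WT_IP passed 0.05 in S200D_IP as well, and none passed with an estimated correlation, with an adjusted p = 0.118 for the LIN28 targets (19 higher and 4 lower of 36, or 19 and 5 adjusted over the list alone, median 0.43), 0.79 for histones (8 and 0 of 16, also adjusted over the list alone, median 0.56) and 0.448 for the other 8. Translation factors had 23 higher and 9 lower of 49 in S200D_IP (median 0.26). With quantile normalization they turned to -0.19 and were lower (adjusted p = 0.0295), and with total reads the call ended (adjusted p = 0.151), with a median of -0.14 that lay 0.19 above that of all genes. The call also ended at a mean of at least 5 RPKM (adjusted p = 0.11). With the length trend removed, the medians in S200D_IP were 0.67 for cytosolic ribosomal proteins, 0.14 for the mitochondrial ribosome, 0.19 for oxidative phosphorylation, 0.13 for translation factors, 0.38 for LIN28 targets and -0.26 for histones. Pluripotency factors had 3 and 12 of 20 (median -0.67), cell-surface, lysosomal and secreted proteins 12 and 39 of 82 (-0.30), ERK feedback genes 1 and 12 of 23 (-0.32) and stress genes 3 and 13 of 26 (-0.43), and the counts of these 5 lists were the same adjusted over the list alone. The LIN28 target call ended with quantile normalization (adjusted p = 0.342) and the pluripotency call with total reads as the scale (adjusted p = 0.125) and without replicate 1 of every group (0.0537). The histone call ended at a mean of at least 5 RPKM (adjusted p = 0.103), without Ctrl_IP replicate 1 (0.0557), without S200D_IP replicate 1 (0.0681) or 3 (0.0585) and without replicate 1 of every group (0.0911). The splicing and RNA-binding protein list missed the threshold (adjusted p = 0.0559) and passed it with lower values with the replicate block (adjusted p = 0.0371), a pseudocount of 0.1 (0.0498), a mean of at least 5 RPKM (0.0176), total reads (0.0141) and quantile normalization (1.57e-08). Among the panel genes, HSPA5 (-1.22 ± 0.12), SOX2 (-0.95 ± 0.13) and CCND1 (-0.92 ± 0.20) were lower and POU5F1 (1.10 ± 0.11) higher.

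**Figure D2:**
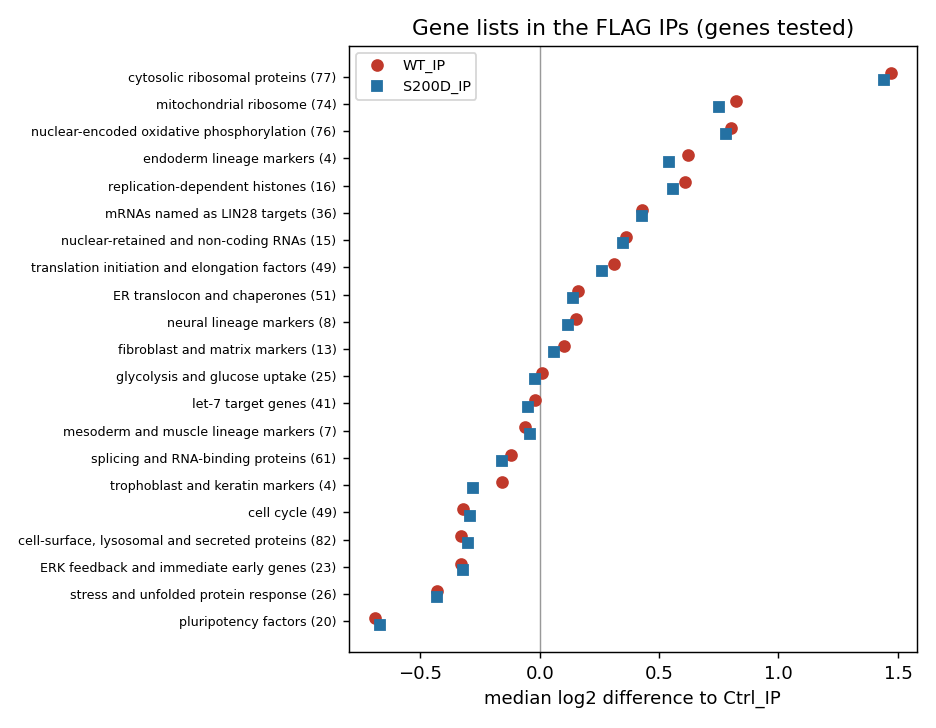
Median log2 difference to Ctrl_IP of each gene list, on the x axis, in WT_IP (circles) and S200D_IP (squares), with the number of genes tested in brackets. The cytosolic ribosomal protein list has the highest median, 1.47 in WT_IP and 1.44 in S200D_IP, and pluripotency factors the lowest, -0.69 and -0.67.

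Of the genes at least 2-fold higher, 972 were shared by the 1030 of WT_IP and the 1012 of S200D_IP, where independent lists would share 89.3. Of the genes at least 2-fold lower, 406 were shared by 481 and 464, where independent lists would share 19.1. Simulated groups with no effect, set against the same controls, had at most 4 genes called, so their 0 shared calls in 20 simulations say nothing of lists of this size. When as many top genes as were called were taken from each simulated group, a step chosen after seeing the data, 349.9 were shared on average among the higher and 141.3 among the lower, and 349.8 and 141.0 with a component shared by libraries of the same number. The shared Ctrl_IP libraries, which are too few to split, may thus give part of the overlap. The simulated groups held no effect, unlike the data, so these numbers cannot say how large that part is. With total reads as the scale 426 higher and 1236 lower genes were shared, with quantile normalization 626 and 547, with median scaling 1155 and 330, and with a pseudocount of 0.1 1133 and 737.

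The direct comparison of S200D_IP with WT_IP asks whether the phospho-mimetic change altered which RNAs were recovered. NDUFB3, RPL9 and LIN28A differed by little between these IPs, as their levels above show, and so did HSPA5, by its differences to Ctrl_IP. Panel genes had log2 differences of -0.06 ± 0.12 for HSPA5, -0.01 ± 0.11 for POU5F1, -0.03 ± 0.13 for SOX2, -0.02 ± 0.20 for CCND1, 0.00 ± 0.13 for HMGA1 and 0.03 ± 0.15 for LIN28B. The count of changed genes by limma was 0, with 63 genes at an unadjusted p under 0.05 and 0 with voom weights on recovered reads. Chance alone would place a share of about 0.05 of the genes there, so the test was conservative. Groups did not overlap for 2.2% of genes, against 10% by chance. The fit leaves out the pairing, while S200D_IP and WT_IP libraries of the same number deviated together (correlations 0.6, 0.62 and 0.58). With the replicate block 0 genes were called too, with 182 at an unadjusted p under 0.05. A test of equivalence on log2(RPKM + 1) placed 99.2% of the 11679 genes within 2-fold and 96.7% within 1.5-fold between the IPs. The added 1 shrinks differences of low genes, so these can pass the margins at larger folds of RPKM. No other pseudocount was tried for equivalence. Of the 1030 genes at least 2-fold higher in WT_IP than in Ctrl_IP, the test placed 99.3% within 2-fold and 97.6% within 1.5-fold. Of the 481 genes at least 2-fold lower, these shares were 91.1% and 75.5%, while the estimate lay within 1.5-fold for 462. Simulated data of this comparison were drawn without the pairing. On them the test found 29.9% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 95.5% of those changed 4-fold.

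Of the gene lists, 5 passed 0.05 in S200D_IP against WT_IP with very small differences and 0 genes called. They were splicing and RNA-binding proteins (median -0.05, camera adjusted p = 0.000656), the mitochondrial ribosome (-0.03, adjusted p = 0.00869), glycolysis and glucose uptake (-0.08, adjusted p = 0.0213), oxidative phosphorylation (-0.03, adjusted p = 0.0232) and translation factors (-0.04, adjusted p = 0.0442). Adjusted over the list alone, 0 genes of these lists were called. Each had an adjusted p = 0.906 with an estimated correlation. Translation factors missed the threshold with a pseudocount of 0.1 (adjusted p = 0.0506) and at a mean of at least 5 RPKM (0.052). With the replicate block they missed it too (adjusted p = 0.064) and fibroblast and matrix markers passed it (adjusted p = 0.0213). The number of lists was 0 without S200D_IP replicate 3, 3 without S200D_IP replicate 2 or WT_IP replicate 3, and 8 without S200D_IP replicate 1. Splicing was not among those 8 (camera adjusted p = 0.124) and missed the threshold without WT_IP replicate 2 as well (0.522). With median scaling glycolysis (0.0527) and oxidative phosphorylation (0.0531) missed it, and with quantile normalization the mitochondrial ribosome did too (0.106). Cytosolic ribosomal proteins, not called with all libraries (adjusted p = 0.648), passed with lower values without S200D_IP replicate 1 (3.4e-19) and with higher values without S200D_IP replicate 2 (3.39e-10), where oxidative phosphorylation turned to higher values as well (0.00348).

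**Figure D3:**
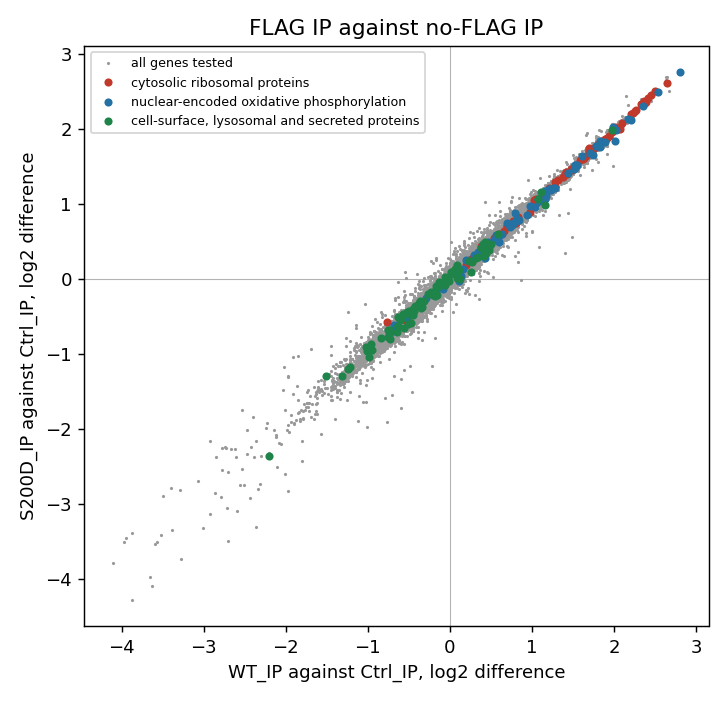
Log2 difference to Ctrl_IP of the 11679 genes tested, in WT_IP on the x axis and in S200D_IP on the y axis, with 3 gene lists in colour. The genes lie along the diagonal, to which the Ctrl_IP libraries shared by both axes contribute. Most cytosolic ribosomal protein and oxidative phosphorylation genes lie above 0 on both axes, and some lie below.

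The inputs ask whether the lines differed in RNA levels before the IP. CD24, a surface sialoglycoprotein, was at 84.7 ± 12.4 RPKM in Ctrl_Input, 8.48 ± 1.06 in WT_Input and 6.65 ± 0.871 in S200D_Input (log2 differences -3.17 ± 0.13 and -3.48 ± 0.13). IGFBP5 (-2.76 ± 0.31), OLIG3, a neural transcription factor (-2.75 ± 0.35), CRABP1, a retinoic acid binding protein (-2.67 ± 0.33), and SOX3 (-2.25 ± 0.23) were lower in WT_Input. LEFTY2, a secreted inhibitor of Nodal signalling (1.94 ± 0.39), TIE1 (1.5 ± 0.19), FGFRL1 (1.29 ± 0.094), ABCG2 (1.24 ± 0.22) and TTYH1 (1.19 ± 0.12) were higher. In S200D_Input, OLIG3 (-2.8 ± 0.35), IGFBP5 (-2.43 ± 0.31), CRABP1 (-2.24 ± 0.33) and CD9 (-1.98 ± 0.19) were lower, and LEFTY2 (1.70 ± 0.39), TIE1 (1.56 ± 0.19), CYP26A1, a retinoic acid hydroxylase (1.47 ± 0.27), FGFRL1 (1.29 ± 0.094) and GNG4 (1.24 ± 0.16) higher. Limma called 442 genes in WT_Input against Ctrl_Input, 250 higher and 192 lower, and 451 in S200D_Input against Ctrl_Input, 285 higher and 166 lower. The balance of directions moved with the scale and the filter, to 199 higher and 233 lower in WT_Input and 195 and 190 in S200D_Input with median scaling, and to 188 and 296 and 216 and 277 without a filter. With the replicate block the counts were 1452 and 1649. Without Ctrl_Input replicate 1, 2 or 3 the WT count was 199, 263 or 159, and without WT_Input replicate 1, 2 or 3 it was 293, 242 or 153. The S200D count was 205, 215 or 147 without Ctrl_Input replicate 1, 2 or 3, and 148 without S200D_Input replicate 3.

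Between S200D_Input and WT_Input, LIN28A differed by 0.00 ± 0.070, and limma called 0 genes, with 65 at an unadjusted p under 0.05 and 0 with voom weights. That number too is below the share of 0.05 that chance alone would give, and groups did not overlap for 2.9% of genes. With the replicate block 0 genes were called, with 317 at an unadjusted p under 0.05. The equivalence test, on the same scale of RPKM + 1, placed 99.7% of genes within 2-fold and 98.1% within 1.5-fold. Cell-surface, lysosomal and secreted proteins were the single list past 0.05 (median 0.03, camera adjusted p = 0.0486; adjusted p = 0.978 with an estimated correlation), with 0 genes called over all genes and 0 adjusted over the list alone. With the replicate block, splicing and RNA-binding proteins (adjusted p = 0.00314) and translation factors (adjusted p = 0.0141) passed as well. The number of lists moved to 9, 2 or 0 without WT_Input replicate 1, 2 or 3, and to 4, 7 or 6 without S200D_Input replicate 1, 2 or 3. The cell-surface call itself ended without WT_Input replicate 3 (camera adjusted p = 0.647) and without S200D_Input replicate 2 (0.0845). Without S200D_Input replicate 1 it ended with its direction turned (0.736).

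Each IP was also set against the input of its own line. In WT_IP, PET100 (2.99 ± 0.13), NDUFB10 (2.91 ± 0.12), RNF7 (2.88 ± 0.080), RPL36AL (2.88 ± 0.10) and NDUFB3 (2.82 ± 0.074) led the increases over WT_Input, and MIR3064 (-4.26 ± 0.31), SNORD78 (-4.05 ± 0.28), SNORD79 (-3.91 ± 0.17), SNORD44 (-3.9 ± 0.45) and SNORD12 (-3.70 ± 0.34) the decreases. In S200D_IP, RNF7 (2.88 ± 0.080), PET100 (2.87 ± 0.13), NDUFB10 (2.86 ± 0.12), RPL36AL (2.84 ± 0.10) and RPS6 (2.8 ± 0.083) led the increases over S200D_Input, and MIR5047 (-4.14 ± 0.31) and SNORD47 (-3.92 ± 0.21) the decreases. Limma called 9144 genes in WT, 4376 higher and 4768 lower, and 9111 in S200D, 4370 higher and 4741 lower. With total reads as the scale, the share of higher genes among them fell to 31.2% in WT and 31.7% in S200D, from 47.9% and 48.0%. It rose to 58.6% and 58.2% with median scaling, to 56.1% in both at a mean of at least 5 RPKM and to 51.7% and 51.9% with quantile normalization. POU5F1 was higher in both (2.00 ± 0.13 and 2.03 ± 0.13), DICER1 (-1.83 ± 0.094 and -1.76 ± 0.094) and HSPA5 (-1.28 ± 0.10 and -1.34 ± 0.10) lower. Across the 11679 genes, which are not independent replicates, the enrichment of WT over input had a correlation of 0.993 with that of S200D, with a slope of 0.996.

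In WT_IP over WT_Input 6 lists passed 0.05, and the same number in S200D_IP over S200D_Input. In WT, cytosolic ribosomal proteins had 73 higher and 1 lower of 77 (median 1.66), the mitochondrial ribosome 70 and 0 of 74 (1.17) and oxidative phosphorylation 68 and 1 of 76 (1.10), with the same counts adjusted over the list alone. Each of the 3 had an adjusted p = 0.621 with an estimated correlation. RPL5 (2.49 ± 0.068) and RPL7 (2.54 ± 0.072) were examples. With quantile normalization the median of the cytosolic ribosomal proteins was 0.17 and its call ended (adjusted p = 0.179). Translation factors had 35 higher and 6 lower of 49 (median 0.68; adjusted p = 0.707 with an estimated correlation), among them EEF1G (2.58 ± 0.081), and turned to a median of -0.19 with quantile normalization, where its call ended (adjusted p = 0.26). Cell-surface, lysosomal and secreted proteins had 8 higher and 62 lower of 82 (median -0.86; adjusted p = 0.494 with an estimated correlation), among them NOTCH3 (-2.90 ± 0.090) and HSPG2 (-2.12 ± 0.071). Of 41 let-7 target genes 10 were higher and 27 lower (median -0.64; adjusted p = 0.712 with an estimated correlation), with IRS2 (-1.99 ± 0.091) and IGF1R (-1.63 ± 0.093) lower and HRAS higher (2.20 ± 0.11). These counts too were the same adjusted over the list alone. The let-7 call ended with total reads as the scale (adjusted p = 0.0543). The no-FLAG IP had low let-7 target values as well, with 4 higher and 18 lower of 41 against Ctrl_Input, or 5 and 18 adjusted over the list alone (median -0.30, camera adjusted p = 0.00171; adjusted p = 0.837 with an estimated correlation). In S200D, the list medians were 1.64, 1.14, 1.05, 0.65, -0.92 and -0.64 in the same order, the first 3 with an adjusted p = 0.665 with an estimated correlation, and the others with 0.706, 0.483 and 0.706. There too the first call ended with quantile normalization (median 0.19, adjusted p = 0.184), translation factors turned to -0.14 and their call ended (adjusted p = 0.295), and the let-7 call ended with total reads (adjusted p = 0.0584).

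The no-FLAG IP recovered background RNA that differed from its input. IL10RB, a cytokine receptor subunit, was at 4.94 ± 0.258 RPKM in Ctrl_Input and 103.1 ± 3.57 in Ctrl_IP (log2 difference 4.13 ± 0.086). RPP25L (3.41 ± 0.12), SPATA7 (2.48 ± 0.13), BRMS1 (2.05 ± 0.12) and VPS4B (2.05 ± 0.12) followed. Very long mRNAs were depleted. PRKDC, a DNA repair kinase, fell from 67.4 ± 4.66 RPKM to 5.58 ± 0.680 (-3.38 ± 0.085), and DYNC1H1 (-3.32 ± 0.095), HUWE1 (-3.13 ± 0.077), FAT1 (-3.11 ± 0.085) and FLNC (-2.92 ± 0.17) were lower too. Limma called 5954 genes, 3006 higher and 2948 lower, of which 51 and 685 changed at least 2-fold. With median scaling there were 4350 higher and 2440 lower, with quantile normalization 3806 and 2795, and without a filter 2835 and 3617, so the balance over all called genes depends on these choices. Gene length had a rank correlation of -0.71 with this difference across 10905 coding genes, of -0.69 with that of WT and of -0.68 with that of S200D. The enrichment of WT over input had a correlation of 0.709 with that of Ctrl across genes, with a slope of 0.403.

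**Figure D4:**
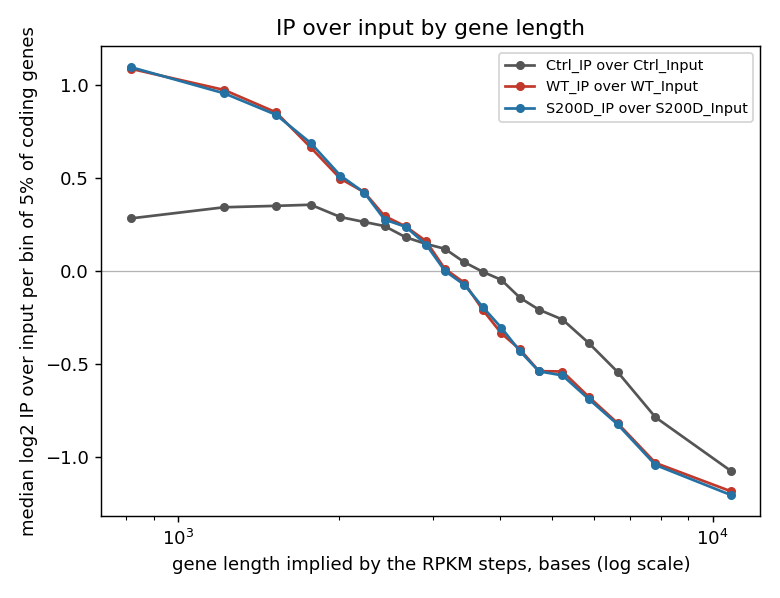
Median log2 difference of IP over input, on the y axis, in bins that each hold 5% of the coding genes, by gene length in bases on a logarithmic x axis, for the Ctrl, WT and S200D lines. The shortest genes have higher values in the WT and S200D lines than in the Ctrl line, whose values change little among short genes, and values of long genes are low in each line.

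The enrichment of each FLAG line over its input was then compared with that of the Ctrl line, which takes the inputs of both lines into account. RNF7 (2.77 ± 0.11), NDUFB3 (2.76 ± 0.11), RPL9 (2.66 ± 0.13), TOMM7, a subunit of the mitochondrial import pore (2.63 ± 0.17), and UQCRH (2.61 ± 0.10) led in WT, and RNF7 (2.77 ± 0.11), NDUFB3 (2.71 ± 0.11), RPL9 (2.69 ± 0.13), SEC11C (2.56 ± 0.12) and UQCRH (2.55 ± 0.10) in S200D. MIR3064 (-4.06 ± 0.44) and MIR5047 (-3.73 ± 0.44) were lowest in WT, and MIR5047 (-4.19 ± 0.44) and MIR3064 (-3.56 ± 0.44) in S200D. POU5F1 was higher (1.32 ± 0.18 and 1.35 ± 0.18), and HSPA5 (-1.28 ± 0.15 and -1.34 ± 0.15) and SOX2 (-1.08 ± 0.20 and -1.12 ± 0.20) were lower. CCND1, lower in the FLAG IPs than in Ctrl_IP, had differences of -0.18 ± 0.29 and -0.20 ± 0.29 here and did not pass the test. Limma called 5833 genes in WT, 2975 higher and 2858 lower, and 5916 in S200D, 2957 higher and 2959 lower. With total reads as the scale the share of higher genes was 22.3% and 23.1%, from 51.0% and 50.0%, and with median scaling it was 61.7% and 61.3%. Without replicate 3 of every group the counts were 3784 and 3941.

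Gene lists were looked at in these 2 comparisons as well, which were not among the planned list comparisons, and 7 passed 0.05 in each. In WT against Ctrl, cytosolic ribosomal proteins had 70 higher and 2 lower of 77, or 72 and 2 adjusted over the list alone (median 1.48, camera adjusted p = 1.39e-27), the mitochondrial ribosome 62 and 1 of 74, or 63 and 1 alone (0.77, 2.99e-15), oxidative phosphorylation 59 and 4 of 76, or 61 and 5 alone (0.80, 1.9e-15), and LIN28 targets 17 and 2 of 36, the same alone (0.42, 0.00113). These 4 had an adjusted p = 0.553 with an estimated correlation. Translation factors had 24 higher and 5 lower of 49, or 26 and 5 adjusted over the list alone (median 0.33, camera adjusted p = 0.00195; adjusted p = 0.639 with an estimated correlation). Cell-surface, lysosomal and secreted proteins had 7 higher and 32 lower of 82 (median -0.33, camera adjusted p = 0.0127) and ERK feedback genes 0 and 11 of 23 (-0.39, 0.0251), both the same adjusted over the list alone and with an adjusted p = 0.613 with an estimated correlation. In S200D against Ctrl the medians were 1.49, 0.76, 0.79, 0.41, 0.35, -0.32 and -0.38 in the same order, with an adjusted p = 0.674 with an estimated correlation for translation factors and 0.577 for the others. With quantile normalization the LIN28 target calls ended (adjusted p = 0.426 in WT and 0.43 in S200D), and translation factors turned to -0.11 and -0.15, where their calls ended. With total reads the ERK call of S200D ended (adjusted p = 0.0566).

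Of the lists called between the FLAG IPs and Ctrl_IP, 3 did not pass here. Replication-dependent histones had 3 higher and 1 lower of 16 in WT (median 0.04, camera adjusted p = 0.665) and 2 and 0 in S200D (0.06, adjusted p = 0.712). Pluripotency factors had 2 higher and 8 lower of 20 in WT (-0.32, adjusted p = 0.0803) and in S200D (-0.29, adjusted p = 0.103). Stress genes had 3 and 10 of 26 in WT (-0.45, adjusted p = 0.0755) and 3 and 11 in S200D (-0.38, adjusted p = 0.0814). The counts were the same adjusted over the list alone. The pluripotency list of WT passed with median scaling (adjusted p = 0.0484), and with quantile normalization the pluripotency (adjusted p = 0.0116 and 0.0178) and stress lists (0.00274 and 0.00404) passed with lower values. The let-7 targets had medians of -0.12 (adjusted p = 0.587) and -0.10 (adjusted p = 0.661) and did not pass.

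For the enrichment of S200D over input against that of WT, limma called 0 genes, with 46 at an unadjusted p under 0.05 and 0 with voom weights. The 46 are again below the chance share of 0.05, and groups did not overlap for 3.2% of genes, so this test was conservative as well. HSPA5 (-0.06 ± 0.15), POU5F1 (0.03 ± 0.18), SOX2 (-0.03 ± 0.20) and LIN28B (0.09 ± 0.19) were examples. The equivalence test, on the same scale of RPKM + 1, placed 98.5% of genes within 2-fold and 93.7% within 1.5-fold. Of the 1030 genes at least 2-fold higher in WT_IP than in Ctrl_IP these shares were 98.9% and 95.2%, and of the 481 at least 2-fold lower 86.1% and 61.5%. On data of this comparison simulated without the pairing, 32.8% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 93.9% of those changed 4-fold were found. The count of gene lists past 0.05 was 0, with the lowest camera adjusted p at 0.368 for splicing and RNA-binding proteins (median -0.03). It was 7 without S200D_IP replicate 1, 5 without S200D_Input replicate 1, 4 without WT_IP replicate 2, 3 without WT_Input replicate 1, S200D_IP replicate 2 or S200D_Input replicate 3, and 2 without WT_Input replicate 2 or 3.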

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

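The tests of library scaling, of RNA levels in the inputs and of small RNA genes with more reads were chosen only after the results were seen, and those of gene length and nuclear RNA before. Intervals of medians are 95% bootstrap intervals over genes, and that of a share is an exact binomial interval. They treat genes as independent and hold no spread between libraries, so they are too narrow as statements on the groups.

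The enrichment over input differed between the WT and Ctrl lines for 5833 genes and between the S200D and Ctrl lines for 5916 genes, by the test of the difference itself in limma. The 12 libraries of each pair of lines form 6 units, each the IP and the input of 1 line with the same replicate number, and the units make 10 splits into groups of 3, too few for a share under 0.05. Every other split gave 0 genes in both comparisons, against the real 5833 and 5916, and 1 of the 10 splits, the real one, reached each count. The replicate numbers pair the units, and the other splits that part every pair of units with the same number, 3 of the 4 such splits with the real one left out, also gave 0. All these other splits mix units of lines that differ, so the difference counts as spread there, and the 0 is no measure of chance.

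Ribosomal protein and mitochondrial mRNAs were higher in both FLAG IPs than in the no-FLAG IP. The tests used the WT and Ctrl lines alone. In WT_IP against Ctrl_IP the median of the 3 lists lay 0.98 above that of all genes (interval 0.84 to 1.07). Library scaling moves every gene alike, save that the added 1 makes low genes move less, so it largely drops out of this distance. The lists were already known to lie higher, so the value was bound to come out this way and cannot weigh scaling. The lists hardly differed between the inputs (median -0.02, interval -0.03 to -0.01), which argues against a change of RNA level in the cells. With the length trend of the other coding genes removed the median was 0.42 (0.29 to 0.54), so length may account for part of the pattern and remains open. Binding by LIN28A, which the design varies through the FLAG transgene, also remains open and was not tested apart from length.

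Values of small non-coding RNA genes were lower in both FLAG IPs, from reads that may belong to longer transcripts, as stated above. In WT_IP against Ctrl_IP the median of these genes lay -0.85 from that of all genes (interval -1.01 to -0.61). Scaling drops out of this distance in part as well, though less so for low genes, so the distance cannot weigh scaling. Of 25 such genes with at least 50 reads per Ctrl_IP library, 23, or 92%, were lower in WT_IP (interval 74% to 99%), so few reads over short genes could still play a part. A low recovery of nuclear RNA was to be tested on 5 nuclear RNAs, but with 3 of them tested the test is void. Their median was -0.94, from MALAT1 (-0.06, adjusted p = 0.737 by limma), NEAT1 (-1.56, adjusted p = 0.000102) and TUG1 (-0.94, adjusted p = 4.02e-05). The wider list of nuclear-retained and non-coding RNAs, given under the other observations, went both ways in WT_IP, with more genes higher than lower, and did not pass the test.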

How the results depend on the processing

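Total reads as the scale, voom weights, overlaps of top simulated genes, shared lower genes on other scales, leaving out small RNA genes and leaving out a replicate number in every group were chosen only after the data were seen. With an estimated correlation 0 lists passed in any comparison, among them the 6 of the 7 fixed list comparisons where lists were called: WT_IP and S200D_IP against Ctrl_IP, S200D_IP against WT_IP, S200D_Input against WT_Input and both FLAG IPs against input. Deviations shared by libraries of the same number enter that estimate, which was not made with the replicate block. A list that misses the threshold with it is thus not shown to be unchanged. The lists of WT_IP against Ctrl_IP numbered 7 at a mean of at least 5 RPKM, where translation factors, stress genes and histones no longer passed, 13 with quantile normalization, 8 with total reads, 8 without Ctrl_IP replicate 1 or WT_IP replicate 3, where stress genes and histones no longer passed, and 9 without replicate 1 of every group. Those of S200D_IP against Ctrl_IP numbered 9 at a mean of at least 5 RPKM, with translation factors and histones ended and splicing started, 13 with quantile normalization, 9 with total reads, 8 to 11 with a replicate number left out in every group and 9 to 11 with a library left out. The lists of S200D_IP against WT_IP numbered 2 with median scaling and 1 with quantile normalization, and from 0 to 8 with a replicate left out. Those of S200D_Input against WT_Input numbered 3 with median scaling, 3 with the replicate block and 3 with total reads, and from 0 to 9 with a replicate left out. In WT_IP and S200D_IP against input, pluripotency factors (adjusted p = 0.00934 and 0.0106) and fibroblast markers (0.0445 and 0.0363) newly passed at a mean of at least 5 RPKM, and LIN28 targets with total reads (0.0253 and 0.0334, from 0.0525 and 0.0627). Quantile normalization gave 10 lists for S200D_IP against S200D_Input, and a left-out replicate 0 to 7 for the enrichment of S200D against WT.

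Genes called in WT_Input against Ctrl_Input numbered 239 at a mean of at least 5 RPKM, with fewer genes tested, 1452 with the replicate block and from 46 to 293 with a replicate left out. Those of S200D_Input against Ctrl_Input numbered 254 at a mean of at least 5 RPKM, 1649 with the replicate block, 288 with all 18 libraries in the fit and from 34 to 399 with a replicate left out. The interactions of WT and S200D with Ctrl had 3784 to 5715 and 3941 to 6021 genes with a replicate left out. Without a filter 1 gene was called in S200D_Input against WT_Input and 1 in the enrichment of S200D against WT, both MIR499A (-0.26, adjusted p = 7.45e-05, and 0.26, adjusted p = 1.6e-08, by limma; mean 0.0327 RPKM), named after its values were seen. Shared higher genes numbered 626 with quantile normalization and 426 with total reads, and shared lower genes 547 and 1236. In Ctrl_IP against Ctrl_Input the replicate block ended the call of cytosolic ribosomal proteins (adjusted p = 0.0334, 0.078 with the block) and passed fibroblast and matrix markers (0.0742 and 0.0396).

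Quantile normalization turned these values. In WT_IP against Ctrl_IP they were HMGA1 -0.10, CDK4 -0.20, GAPDH -1.12, ACTB -1.20, ATF4 -0.23, YBX1 -0.21 and PGAM1 -0.01. In S200D_IP against Ctrl_IP they were HMGA1 -0.07, CDK4 -0.16 and GAPDH -1.19. In WT_IP against input they were CDK4 -0.15, CCNB1 -0.82, GAPDH -0.85 and ACTB -1.29, and in S200D_IP against input CDK4 -0.09, CCNB1 -0.83, GAPDH -0.90 and ACTB -1.35. ACTB in Ctrl_IP against input was -0.08. In the interaction of WT with Ctrl they were CDK4 -0.25, GAPDH -1.05 and ACTB -1.22, and in that of S200D with Ctrl HMGA1 -0.03, CDK4 -0.19 and GAPDH -1.10. Total reads as the scale turned ACTB in WT_IP against Ctrl_IP (-0.39), CCNB1 in WT_IP and S200D_IP against input (-0.37 and -0.37) and IGF2BP1 in both interactions (-0.35 and -0.33). Apart from changes of scale, the cause of these changes was not tested. Of the values of 380 named results, alternatives fixed in advance left 5530 on the same side of the threshold and direction, 159 no longer passed, 63 newly passed, 18 moved and 25 turned, and those chosen later 2085, 85, 33, 14 and 5. Small RNA genes, with a median of 9.3 reads per Ctrl_IP library, are where depth limits the values.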

Other observations

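The test of the length trend in each line, that of RNA levels in the inputs and the hydropathy threshold of 1.6 were chosen only after the results were seen, and the lists of the inputs against Ctrl_Input and of the no-FLAG IP were not among the planned list comparisons. Intervals are again bootstrap intervals over genes, which hold no spread between libraries.

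Replication-dependent histone genes had higher values in the inputs of both FLAG lines than in Ctrl_Input, with a median of 0.41 in WT_Input (camera adjusted p = 0.000536; adjusted p = 0.921 with an estimated correlation) and 0.44 in S200D_Input (camera adjusted p = 0.000315; adjusted p = 0.927 with an estimated correlation). By limma 1 of 16 was higher in each, or 2 adjusted over the list alone. HIST1H2BC, at 1.16 ± 0.464 RPKM in Ctrl_Input and 3.10 ± 0.658 in WT_Input, differed by 0.93 ± 0.20 in WT. These are values of polyA-selected RNA, and histone RNA without a polyA tail was not measured. The other lists past 0.05 differed by little and were lower: in WT_Input cytosolic ribosomal proteins (-0.03, camera adjusted p = 0.0182), oxidative phosphorylation (-0.02, 0.0333), translation factors (-0.03, 0.0333) and nuclear-retained and non-coding RNAs (-0.14, 0.0409), each with an adjusted p = 0.921 with an estimated correlation, and in S200D_Input the same lists (-0.04, 0.00169; -0.03, 0.00823; -0.05, 0.00169; -0.14, 0.0426), with 0.927. Of their genes 0 were called, also adjusted over the list alone, save 1 lower translation factor in each input, or 0 in WT_Input adjusted over the list alone. With quantile normalization the calls of the first 3 in WT_Input and of the first in S200D_Input ended. Among 4 endoderm markers tested, GATA4, a transcription factor of early endoderm, was higher in WT_Input (0.78 ± 0.085, adjusted p = 0.00172 by limma) and 1 of 4 was called, or 2 adjusted over the list alone. In WT_IP against Ctrl_IP 2 of the 4 endoderm markers were higher and 0 lower, and of 4 trophoblast and keratin markers 1 was higher and 2 lower, with the same counts adjusted over the list alone.

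In the no-FLAG IP against its input, cell-surface, lysosomal and secreted proteins had 9 higher and 45 lower of 82, or 9 and 47 adjusted over the list alone (median -0.50, camera adjusted p = 2.96e-07; adjusted p = 0.402 with an estimated correlation). HSPG2, a matrix proteoglycan (-2.34 ± 0.071), NOTCH2 (-2.36 ± 0.077) and IGF2R, a receptor of lysosomal enzymes (-2.45 ± 0.098), were lower. Stress and unfolded protein response genes had 13 higher and 3 lower of 26, also adjusted over the list alone (median 0.37, camera adjusted p = 0.0247; adjusted p = 0.837 with an estimated correlation), among them ATF4 (0.83 ± 0.084) and HSPB1 (0.78 ± 0.12). The other lists that passed were the mitochondrial ribosome with 51 higher and 1 lower of 74 (median 0.36, camera adjusted p = 8.67e-08), oxidative phosphorylation with 37 and 3 of 76 (0.21, 0.000451), translation factors with 25 and 6 of 49, or 27 and 6 adjusted over the list alone (0.28, 0.00452), cytosolic ribosomal proteins with 26 and 5 of 77 (0.13, 0.0334) and let-7 targets with 4 and 18 of 41, or 5 and 18 adjusted over the list alone (-0.30, 0.00171). Each had an adjusted p = 0.837 with an estimated correlation, and where no other counts are given those adjusted over the list alone were the same. The ribosome, oxidative phosphorylation and translation lists higher in the FLAG IPs are thus higher over input in the no-FLAG IP too, by less. With quantile normalization cytosolic ribosomal proteins turned to -0.15 (adjusted p = 0.000927), and the calls of oxidative phosphorylation (0.686), translation factors (0.761) and stress genes (0.0958) ended. With the replicate block the call of cytosolic ribosomal proteins ended (adjusted p = 0.078), and fibroblast and matrix markers, with 2 higher and 7 lower of 13 (-0.62, adjusted p = 0.0742), passed (adjusted p = 0.0396).

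Several lists did not pass the test in WT_IP against Ctrl_IP. Of 41 let-7 targets 12 were higher and 13 lower (camera adjusted p = 0.729), of 61 splicing and RNA-binding proteins 12 and 23, or 12 and 22 adjusted over the list alone (0.179), of 51 genes of the ER translocon and chaperones 21 and 13, or 21 and 14 adjusted over the list alone (0.308), of 25 glycolysis genes 10 and 7 (0.945), and of 49 cell cycle genes 12 and 25 (0.189). Of 8 neural markers 1 was higher and 2 lower, with a median of 0.15, a mean of -0.38 and a test in the direction of the mean (0.929). Of 15 nuclear-retained and non-coding RNAs 8 were higher and 4 lower, with a median of 0.36, a mean of -0.05 and a test in the direction of the median (0.73). Where no other counts are given, those adjusted over the list alone were the same. With quantile normalization the splicing (adjusted p = 5.33e-08), ER (0.0416), glycolysis (0.0131) and cell cycle (0.000214) lists passed with lower values, with medians of -0.65, -0.23, -0.20 and -0.51, and the splicing list also did with total reads as the scale (adjusted p = 0.0358). Mesoderm markers had 1 higher and 1 lower of 7, or 0 and 0 adjusted over the list alone (0.983), and fibroblast markers 4 and 2 of 13 (1).

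The lower values of cell-surface, lysosomal and secreted protein mRNAs in the FLAG IPs were weighed against technical explanations. The list had a median of 0.02 between WT_Input and Ctrl_Input (interval -0.05 to 0.05), which argues against RNA levels in the cells. With the length trend of the other coding genes removed its median in WT_IP against Ctrl_IP was -0.24 (interval -0.32 to -0.08), so length may account for part and remains open. A hypothesis that mRNAs of proteins with a hydrophobic segment are lower was tested over the other coding genes. The 1900 with a segment differed from the 8898 without by -0.01 (interval -0.04 to 0.03) at a hydropathy threshold of 2.0, and 3335 from 7463 by -0.04 (interval -0.06 to -0.01) at 1.6, a threshold chosen after the value of HSPA5 was seen, and neither reached the predicted -0.1.

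A hypothesis that the density of GGAGA, a motif known from LIN28 binding, goes with higher values in the FLAG IPs was negative. Among the 10 orders of its bases GGAGA ranked 5 by rank correlation with the length-corrected difference across 10881 genes (0.029, against 0.047 for GGGAA). Length had rank correlations with IP over input of -0.71, -0.69 and -0.68 in the Ctrl, WT and S200D lines, so the low values of long mRNAs in the no-FLAG IP may belong to a length trend of the procedure.

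Each comparison of 3 with 3 libraries, or of 3 with 3 units of an IP and its input for the enrichment of S200D against WT, has 10 splits, too few for a share under 0.05. For genes, 1 split, the real one, reached the real count for WT_IP and S200D_IP against Ctrl_IP (6833 and 6822), WT_Input and S200D_Input against Ctrl_Input (442 and 451) and the IPs against the inputs of the WT, S200D and Ctrl lines (9144, 9111 and 5954), and the highest other was 0. These other splits mix groups that differ, so the difference counts as spread there, and the 0 is no measure of chance. With a real count of 0, all 10 reached it for S200D_IP against WT_IP (highest other 2, and 0 among those that part every pair), S200D_Input against WT_Input (highest other 0) and the enrichment of S200D against WT (highest other 0). For lists, 3 splits had as many as the real 10 for WT_IP against Ctrl_IP (highest other 12, and 8 among those that part every pair), 2 as many as 10 for S200D_IP against Ctrl_IP (10 and 10), 8 as many as 5 for S200D_IP against WT_IP (10 and 10), 10 as many as 1 for S200D_Input against WT_Input (12 and 5), 9 as many as 6 for WT_IP against WT_Input (9 and 6), 9 as many as 6 for S200D_IP against S200D_Input (8 and 7) and 10 as many as 0 for the enrichment of S200D against WT (10 and 7). The splits that part every pair number 4 with the real one, and the others set libraries of the same number together. Among the inputs the highest other split called 12 lists, against 1 for the real one. In every list comparison the highest other reached or passed the real count. Where the groups differ, the other splits mix them unevenly and keep part of the difference, which the list test can call. Their list counts are thus no measure of chance there, and list counts at the preset correlation cannot set the real grouping apart. Among the inputs the highest other falls from 12 to 5 among splits that part every pair, so the pairing may account for part of the excess. Its cause was not tested, and with an estimated correlation the real call ends (adjusted p = 0.978).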
